A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

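Poly(A)-selected RNA from 6 budding yeast strains was sequenced, with 3 cultures per strain grown and processed separately, per the labels, giving 18 libraries. The strain called WT here carries a chromosomal deletion of RAD6 and a centromeric TRP1 plasmid with an epitope-tagged wild-type RAD6. The P43L, P47T and E49K strains carry the same plasmid with 1 amino acid of Rad6 replaced, and the rad6Δ strain carries the empty vector. The bre1Δ strain lacks BRE1, carries the empty vector and keeps its own untagged chromosomal RAD6. The bre1Δ strain therefore differs from WT in the source and tag of Rad6 as well as in BRE1. Cells were grown at 30 °C in synthetic medium lacking tryptophan, which selects for the plasmid. The protocols give 2 different culture densities at harvest, and which applied was not settled here. Libraries were made with a stranded kit and read as single 50-base reads, per the labels' protocols. A ribosomal RNA depletion kit that the protocol mentions for 2 other strains was not used for any of the 6 strains analysed here.

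The authors deposited a table of raw counts, whole-number reads per gene for each library. Per the submitters' processing notes, the tools were cutadapt 1.16, STAR 2.6.1b, featureCounts 1.6.3 of the Subread package and DESeq2 1.20, with the builds sacCer3 and R64. Their settings, including whether counting used strand and how multiply mapped reads were treated, are not given in the sources used here. Reads shared by near-identical copies (pairs of ribosomal protein genes, TDH, ENO, PDC and HXT genes, COS, FLO and VEL1 among others) may therefore be split or lost, and the values of such genes are uncertain. The same holds for overlapping genes, such as the intron-encoded mitochondrial genes BI3, BI4, AI1 and AI5_ALPHA, the pair SNR7-L and SNR7-S, and 21S_RRNA with SCEI, and for genes with a transcript on the opposite strand. The authors also deposited regularized log2 values (rlog), which were used here only as a check. Their lowest correlation with log2 counts in any library was 0.993.

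The count table held 5746 genes, and 3 further lines without values were not analysed here. Gene identifiers were matched to the R64 annotation by locus tag for 5633 genes and by symbol for 90, and 23 were not matched. The table held 5608 nuclear open reading frames, 112 nuclear noncoding genes and 26 mitochondrial genes. Library totals ran from 5065845 to 11396251 counts. Replicate libraries differed by more than counting noise in every pair (chi-square per degree of freedom from 6.42 to 41.3), so all 18 were kept as separate replicates.

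Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 5630 and removed 116. TMM factors, from 0.896 to 1.07, scaled the library totals, and one quasi-likelihood model with robust dispersion was fitted to all 18 libraries (12 residual degrees of freedom, biological coefficient of variation 8.55%). Each comparison was tested with glmQLFTest, two-sided, and p-values were adjusted within the comparison by the Benjamini-Hochberg method, with a threshold of 0.05. Every adjusted p of a single gene in the text comes from this test. Verbs of change are used for genes past this threshold. Log2 fold changes are printed ± their standard error, from the fold change and its F statistic. CPM values are counts scaled by the TMM-corrected library total, printed as mean ± SD over 3 libraries. The 5 mutants were each compared with WT, the 3 point mutants and bre1Δ with rad6Δ, and the point mutants with one another, 12 comparisons in all.

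Gene lists, 32 in number, were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the alternatives. The cell wall list holds MLP1, by symbol a nuclear pore gene, which was kept because the list was fixed. One list, of retrotransposons, had no tested gene, and 31 were tested with camera (limma 3.58.1) against all other genes, with a preset correlation of 0.01 and adjustment over 155 tests. The tests were repeated with a correlation estimated for each list. The same lists were tested in the 7 comparisons between mutants (217 tests), a choice made after seeing the data. Named genes were RAD6 and BRE1 in every strain. They also included the 5 highest and 5 lowest fold changes against WT (3 and 3 between mutants) among called genes with a mean of at least 10 CPM in the higher group and no overlap between the groups' values, leaving out RAD6, BRE1 and genes without a symbol of their own. Up to 4 members with the lowest adjusted p were named from each list described. A fixed set was named whatever its values: PTR2, CUP9, UBR1, HTB1, HTB2, PHO5, PHO84, GAL1, FLO11, ARG1, SUC2, RNR3, MFA1, HMLALPHA1 and STE3. MFA1 did not pass the filter, and HMLALPHA1 is not analysed here.

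All 5 comparisons with WT share the same 3 WT libraries. All 18 libraries, WT included, were simulated with no effect (20 simulations), so that the comparisons shared a simulated WT group. Genes varied independently there, and a shift common to many genes in the real WT libraries was not simulated. The simulations gave the shared calls, correlation and covariance that arise from such noise alone. The slope of one mutant's log2 fold changes on those of another was taken over all tested genes and corrected for the shared WT error with that simulated covariance. The WT libraries are too few to be divided between comparisons. The procedure was tested on simulated counts for E49K against WT over 5630 genes. It recovered 31 of 50 genes changed 1.3-fold, 46 of 50 changed 1.5-fold, 50 of 50 changed 2-fold and 49 of 50 changed 4-fold, and 10 of its 186 calls were false. Alternatives were DESeq2 1.42.0, other scaling, other filters, fits of only the groups compared, a replicate block, stricter thresholds and leaving out each library. After seeing the data, alternatives were added that left out the 3 libraries farthest from their own group, or kept nuclear open reading frames alone, or thinned all libraries to the lowest total. Figures and table work used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.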

Results

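RNA was measured in 6 strains of budding yeast to follow how gene expression depends on Rad6, a ubiquitin-conjugating enzyme, and on the beta-turn on its backside that the P43L, P47T and E49K substitutions alter. With the ubiquitin ligase Bre1, Rad6 attaches ubiquitin to histone H2B, and with the ligase Ubr1 it marks proteins for degradation. The null strains rad6Δ and bre1Δ lack the enzyme and the ligase. Each strain had 3 libraries, so n = 3 for every group mean. Library totals ran from 5065845 counts (WT replicate 3) to 11396251 (P47T replicate 1). Nuclear noncoding genes took 20.2% ± 2.20 of the counts in WT, 22.4% ± 2.13 in rad6Δ, 20.0% ± 2.12 in bre1Δ, 18.6% ± 2.75 in P43L, 18.3% ± 1.21 in P47T and 18.5% ± 0.532 in E49K (SD, n = 3). The signal recognition particle RNA SCR1 alone held 5.67% of all counts, and the U2 spliceosomal RNA LSR1 3.55%. The RNA was described as poly(A)-selected, while most nuclear noncoding RNAs lack a poly(A) tail. How they came to hold these shares was not tested, and their values may depend on how well the selection worked.

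The deleted genes were checked first. RAD6 (YGL058W, chromosome VII, 393986 to 394504 in R64, a protein-coding gene on the plus strand) had 149 ± 6.82 CPM in WT and 4.29 ± 0.510 CPM in rad6Δ (log2 fold change −5.12 ± 0.13, adjusted p = 5.34e-18). It had 127 ± 17.3 CPM in P43L (−0.24 ± 0.09, adjusted p = 0.077) and 162 ± 15.3 CPM in P47T (0.12 ± 0.09, adjusted p = 0.348), neither past the threshold. In E49K, RAD6 averaged 175 CPM (0.23 ± 0.09, adjusted p = 0.0499), a call lost when any 1 of the 6 libraries was left out and under DESeq2. In bre1Δ, where RAD6 is read from the chromosome, it was lower than in WT, at 101 ± 6.90 CPM (−0.56 ± 0.09, adjusted p = 6.54e-05). BRE1 (YDL074C, chromosome IV, 324047 to 326149, minus strand) had 141 ± 5.67 CPM in WT and 1.72 ± 0.436 CPM in bre1Δ (−6.38 ± 0.13, adjusted p = 4.71e-20). Its mean lay between 129 and 144 CPM in the other mutants, with no call. Transcripts specific to mating type did not match the mating type in the genotype labels, which is a. The alpha-factor gene MF(ALPHA)1 had 1122 to 1960 CPM in all 18 libraries, while the a-factor genes MFA1 and MFA2 together had 0.14 to 3.31 CPM.

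**Figure D1:**
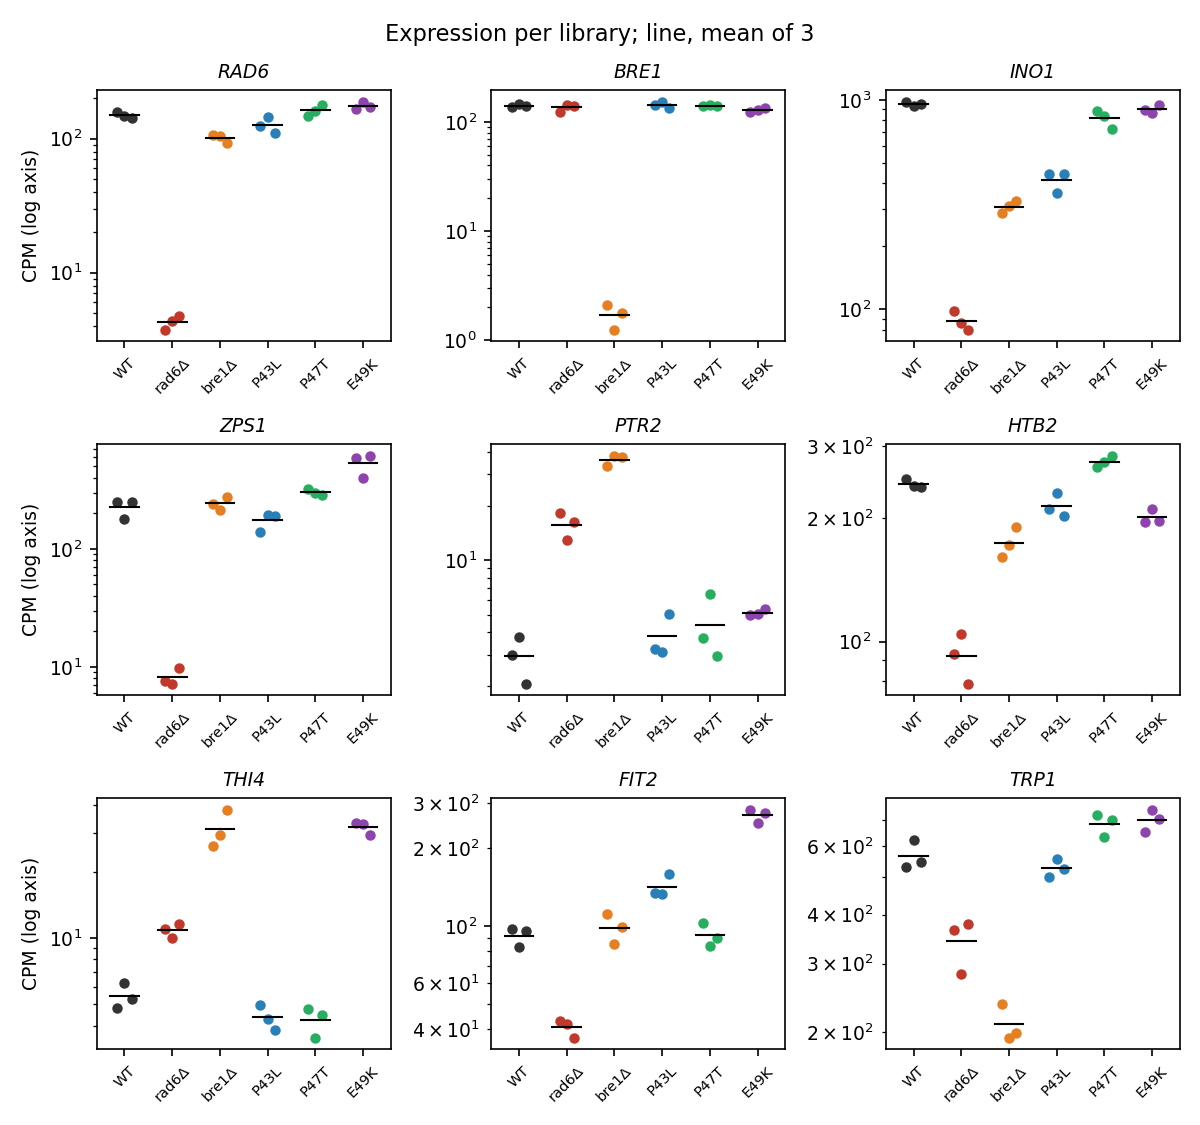
CPM of 9 genes in each of the 18 libraries on log axes, with points for libraries, colors for strains and a line at the mean of 3. RAD6 is low in rad6Δ (4.29 CPM) and BRE1 in bre1Δ (1.72 CPM), INO1 is lowest in rad6Δ (88.0 CPM), and THI4 is highest in E49K and bre1Δ (31.8 and 31.2 CPM).

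The first principal component of log2 CPM held 40.7% of the variance and placed the rad6Δ libraries at 21.8 to 22.2 and the bre1Δ libraries at 13.4 to 15.7. E49K lay between these and WT, at −1.62 to −0.69, with WT at −10.8 to −9.31. P43L (−12.5 to −11.5) and P47T (−14.1 to −12.7) lay on the far side of WT. The second component held 15%, and on it 3 libraries stood apart from their own group. P43L replicate 2 was at −8.42 against −1.31 and −1.58, bre1Δ replicate 3 at 11.2 against −3.68 and 0.31, and P47T replicate 3 at 3.71 against 12.4 and 9.96. P43L replicate 2 also had 21.7% of its counts in noncoding genes, against 16.6% and 17.3% in the other P43L libraries.

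**Figure D2:**
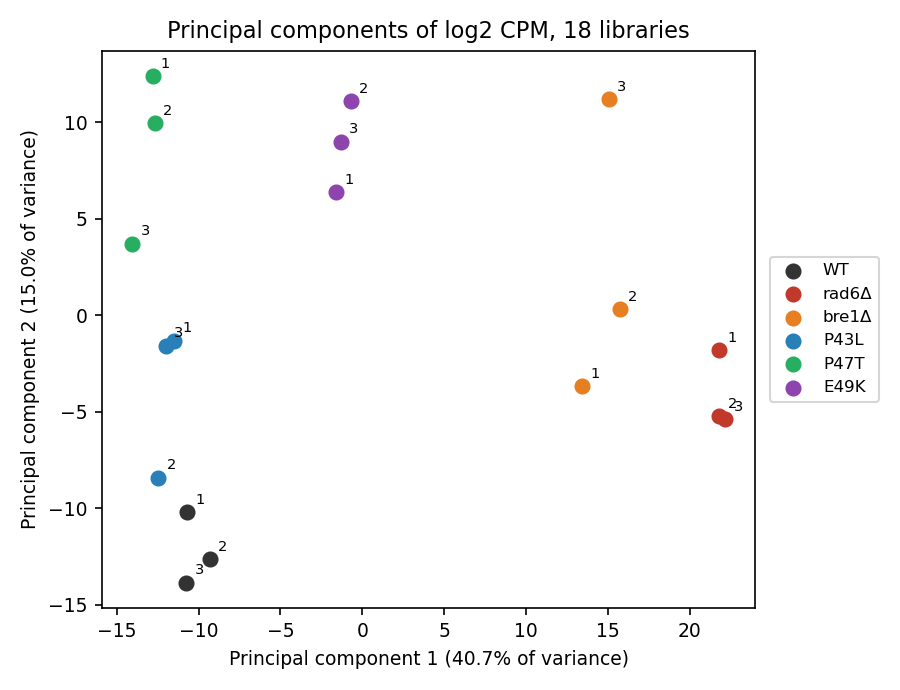
Principal components 1 (40.7% of the variance) and 2 (15%) of log2 CPM, with one point per library, colored by strain and numbered by replicate. The null strains lie at the right (13.4 to 22.2), and E49K (−1.62 to −0.69) lies between them and the other strains.

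Loss of Rad6 was compared with WT. The first 5 genes below had the lowest fold changes among those that met the naming rule. ZPS1 (YOL154W, chromosome XV, 34658 to 35407), a cell wall protein gene induced when zinc is low, fell from 227 ± 41.1 to 8.22 ± 1.39 CPM (−4.80 ± 0.22, adjusted p = 7.42e-11). INO1 (YJL153C, chromosome X, 134332 to 135933), which encodes inositol phosphate synthase, fell from 955 ± 21.4 to 88.0 ± 9.27 CPM (−3.44 ± 0.11, adjusted p = 2.41e-16). The zinc transporter gene ZRT1 fell from 1518 ± 129 to 358 ± 22.1 CPM (−2.08 ± 0.10, adjusted p = 7.79e-13), and ADH4 fell by 1.85 ± 0.17 and PGM2 by 1.68 ± 0.10 on the log2 scale. Of those with the highest fold changes under that rule, the malate synthase gene MLS1 (chromosome XIV, 406358 to 408022) went from 3.43 ± 0.256 to 22.3 ± 1.71 CPM (2.68 ± 0.16, adjusted p = 4.21e-11). The di- and tripeptide transporter gene PTR2 (chromosome XI, 615730 to 617535) went from 2.93 ± 0.840 to 15.8 ± 2.67 CPM (2.36 ± 0.23, adjusted p = 4.18e-08). BSC1 (2.68 ± 0.55), PRM7 (2.47 ± 0.46) and CSS1 (2.24 ± 0.25) rose as well. In all, 2796 genes changed in rad6Δ, 1399 up and 1397 down, 262 of them at least 2-fold (179 up, 83 down). The values of rad6Δ and WT did not overlap in 2712 of the called genes, and in 3376 of all tested genes, where chance gives 10% of them.

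Histone genes fell in rad6Δ: of 11 tested, 10 fell and 1 rose, over all genes and adjusted over the list alone (camera adjusted p = 1.07e-06, adjusted p = 0.0326 with an estimated correlation). The H2B gene HTB2 (chromosome II, 236492 to 236887) fell from 242 ± 6.28 to 92.2 ± 12.6 CPM (−1.39 ± 0.09, adjusted p = 6.31e-11), HHF1 fell by 1.09 ± 0.09, HHF2 by 0.95 ± 0.07 and HTB1 by 0.67 ± 0.08. The 1 histone gene that rose was CSE4, the centromeric variant of H3, named after its value was seen (0.35 ± 0.11, adjusted p = 0.0105). Of 39 genes of the environmental stress response and storage carbohydrate list, 31 fell and 4 rose (31 and 5 adjusted over the list alone; camera adjusted p = 2.14e-13, adjusted p = 0.159 with an estimated correlation). They included the catalase gene CTT1 (−1.44 ± 0.09), the glycogen synthase gene GSY1 (−1.27 ± 0.09) and the glycogen branching gene GLC3 (−1.21 ± 0.09). The zinc regulon had 10 falls and 1 rise among 14 genes, the same numbers adjusted over the list alone (camera adjusted p = 5.42e-11, adjusted p = 0.147 with an estimated correlation). Iron genes fell too, 15 of 26 with 1 rise (16 and 1 adjusted over the list alone), TIS11 by 1.26 ± 0.10, FIT2 by 1.18 ± 0.11, MRS4 by 0.97 ± 0.08 and FET3 by 0.83 ± 0.09 (camera adjusted p = 0.000427, adjusted p = 0.234 with an estimated correlation).

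Several groups rose in rad6Δ. Meiosis and sporulation genes, which vegetative cells keep low, rose in 27 of 41 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 3.80e-06, adjusted p = 0.144 with an estimated correlation). Examples were LOH1 (2.01 ± 0.18), CDA1 (1.90 ± 0.23), SPO74 (1.64 ± 0.22) and the meiotic cohesin gene REC8 (1.36 ± 0.14). Before the count filter this list held 46 genes. The filter can keep a low gene through a strain where it is high, and how far this favored the call was not tested. Ribosome biogenesis genes rose in 45 of 65 cases with no fall (46 adjusted over the list alone; camera adjusted p = 2.36e-09, adjusted p = 0.366 with an estimated correlation). Among them were PWP1 (0.89 ± 0.10), DBP10 (0.84 ± 0.10), NOP12 (0.81 ± 0.08) and NOP2 (0.75 ± 0.08). Genes under nitrogen catabolite repression rose in 16 of 24 cases and fell in 1 (17 and 1 adjusted over the list alone; camera adjusted p = 3.80e-06, adjusted p = 0.159 with an estimated correlation). The arginase gene CAR1 was at 1.42 ± 0.11, the ammonium permease gene MEP2 at 1.26 ± 0.11 and GLN1 at 0.90 ± 0.09. Of 30 glucose-repressed genes 18 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 6.81e-05, adjusted p = 0.144 with an estimated correlation). MLS1, POT1 (2.06 ± 0.21) and MDH2 (0.67 ± 0.07) were higher, while the hexose transporter gene HXT7, which shares reads with HXT6, was lower (−1.18 ± 0.13). The a-specific genes rose in 4 of 5 cases, also adjusted over the list alone (camera adjusted p = 0.0301, adjusted p = 0.256 with an estimated correlation): AGA2 (2.10 ± 0.37, from 0.617 to 2.72 CPM), MFA2 (2.00 ± 0.49, from 0.416 to 1.59 CPM), BAR1 (1.31 ± 0.21) and STE2 (0.65 ± 0.13), the first 2 near the floor, in cells whose alpha-factor transcripts exceeded those of a-factor at least 450-fold in each library. AGA2 and MFA2 had at most 1.41 and 0.764 CPM in the other strains, so the count filter kept them mainly through rad6Δ, which favors this list call. The list held 7 genes before the filter.

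The other lists called in rad6Δ passed with the preset correlation and not with an estimated one. They were cell wall integrity (15 of 31 up, 5 down, adjusted p = 0.0166, adjusted p = 0.578 with an estimated correlation), subtelomeric families (11 of 34 up, 2 down, 0.0259 and 0.234) and stress chaperones (13 of 25 up, 4 down, 0.0282 and 0.300). They had the same counts adjusted over the list alone. The N-degron and peptide import list (5 of 10 up, 2 down, adjusted p = 0.147) and genes within 20 kb of a chromosome end (48 of 135 up, 24 down, adjusted p = 0.113; 49 and 24 adjusted over the list alone) were not called. No call was made for the H2B ubiquitination pathway (4 of 22 up, 6 down, adjusted p = 0.875), whose median (0.00) and mean (−0.03) differed in sign. The DNA damage response (9 of 23 up, 6 down, adjusted p = 0.337), the phosphate regulon (8 of 19 up, 3 down, 9 and 4 adjusted over the list alone, adjusted p = 0.101) and the galactose genes (2 of 10 up, 2 down, adjusted p = 0.154) were not called either. Single members did change: the phosphatase gene PHO5 rose (0.73 ± 0.10, adjusted p = 6.64e-06), as did the ribonucleotide reductase gene RNR3 (0.77 ± 0.14, adjusted p = 0.000136). The phosphate transporter gene PHO84 rose from 0.547 ± 0.211 to 3.91 ± 0.559 CPM (2.89 ± 0.38), low levels in a gene that overlaps the noncoding gene YNCM0001W. The peptide transport regulator gene CUP9 fell (−0.48 ± 0.10, adjusted p = 0.000318), as did ARG1 (−0.53 ± 0.09, adjusted p = 5.01e-05), and UBR1 rose (0.31 ± 0.08, adjusted p = 0.00277). GAL1 (−0.23 ± 0.25), FLO11 (−0.02 ± 0.25) and SUC2 (−0.08 ± 0.08) were not called here or in any other mutant against WT.

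Loss of Bre1 was compared with WT in the same way. PTR2 rose to 36.1 ± 2.53 CPM (3.56 ± 0.21, adjusted p = 1.04e-10), more than in rad6Δ. The thiamine synthesis gene THI4 (chromosome VII, 780399 to 781379) rose from 5.46 ± 0.753 to 31.2 ± 6.20 CPM (2.50 ± 0.15, adjusted p = 1.29e-10), and VEL1, a subtelomeric gene with a near-identical copy, rose by 3.01 ± 0.42. PRM7 (2.36 ± 0.48) and MLS1 (2.28 ± 0.17) rose too. INO1 fell to 310 ± 20.1 CPM (−1.63 ± 0.10, adjusted p = 1.16e-10), as did FMP16 (−1.60 ± 0.23), the plasmid marker gene TRP1 (−1.43 ± 0.11), GEP7 (−1.28 ± 0.17), which lies beside RAD6, and CTT1 (−1.28 ± 0.09). In all, 2501 genes changed, 1257 up and 1244 down, 123 at least 2-fold (106 up, 17 down). With library totals alone the split was 734 up and 1699 down, and the median of all genes moved to −0.11. Values of bre1Δ and WT did not overlap in 2313 called genes and in 50.5% of tested genes (10% by chance).

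Ribosome biogenesis rose in bre1Δ, with 56 of 65 genes up and none down (58 adjusted over the list alone; camera adjusted p = 6.18e-19, adjusted p = 0.223 with an estimated correlation). Examples were PWP1 (0.87 ± 0.10), NOP12 (0.80 ± 0.08), BRX1 (0.75 ± 0.08) and NOP2 (0.74 ± 0.08). Ribosomal protein genes rose in 77 of 137 cases with 1 fall (81 and 1 adjusted over the list alone, 46 and 2 with library totals alone; camera adjusted p = 1.16e-07, adjusted p = 0.436 with an estimated correlation). RPS14B rose by 0.99 ± 0.10 and RPS24A by 0.62 ± 0.12, with reads of such gene pairs uncertain. Stress and storage carbohydrate genes fell in 29 of 39 cases and rose in 3 (30 and 3 adjusted over the list alone; camera adjusted p = 3.53e-12, adjusted p = 0.172 with an estimated correlation). Among them were MSC1 (−1.24 ± 0.09), RTN2 (−1.09 ± 0.11) and PGM2 (−0.98 ± 0.10). Thiamine synthesis genes rose in 13 of 18 cases with no fall, also adjusted over the list alone (camera adjusted p = 3.42e-05, adjusted p = 0.172 with an estimated correlation). THI73 rose (adjusted p = 2.99e-07), with PET18 at 0.56 ± 0.09 and THI2 at 0.46 ± 0.08 beside THI4. Meiosis genes rose in 20 of 41 cases and fell in 2, also adjusted over the list alone (camera adjusted p = 0.000386, adjusted p = 0.207 with an estimated correlation). SPS1 rose by 1.71 ± 0.23, CDA1 by 1.57 ± 0.24 and SPO74 by 1.55 ± 0.23. Glycolysis genes rose in 10 of 17 cases with no fall, also adjusted over the list alone (camera adjusted p = 0.00154, adjusted p = 0.567 with an estimated correlation). Examples were ENO2 (0.84 ± 0.16) and PDC5 (0.74 ± 0.16). Pheromone response and haploid-specific genes fell in 12 of 25 cases and rose in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.0111, adjusted p = 0.207 with an estimated correlation). SST2 was at −0.69 ± 0.09, GPA1 at −0.58 ± 0.08, FAR1 at −0.55 ± 0.09 and AXL1 at −0.52 ± 0.07.

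The other 8 of the 15 lists called in bre1Δ also passed only with the preset correlation. Their counts were the same adjusted over the list alone, except for the proteasome (10 down). With library totals alone, Gcn4 amino acid genes had 13 rises and 7 falls, sulfur genes 8 and 4, cell wall genes 9 and 2, glucose-repressed genes 10 and 4, N-degron genes 3 and 1, alpha-specific genes 0 and 5, respiration genes 1 and 22 and proteasome genes 0 and 20. Genes rose mainly in Gcn4 amino acid biosynthesis (23 of 52 up, 3 down, adjusted p = 0.00117, adjusted p = 0.565 with an estimated correlation), cell wall integrity (15 of 31 up, 2 down, 0.00134 and 0.456) and sulfur amino acid metabolism (14 of 30 up, 3 down, 0.0166 and 0.256). The same held for the N-degron and peptide import list (4 of 10 up, 0.0239 and 0.256), whose median turned from 0.05 to −0.07 with library totals alone, and for glucose-repressed genes (13 of 30 up, 2 down, 0.0257 and 0.277), a call lost without bre1Δ replicate 1. Genes fell mainly in the alpha-specific list (4 of 5, 0.0159 and 0.159), respiration and the TCA cycle (14 of 43 down, 2 up, 0.0239 and 0.430; lost without WT replicate 1 or bre1Δ replicate 2) and the proteasome (11 of 33, 0.0282 and 0.234). Among the genes followed in every strain, HTB2 fell (−0.48 ± 0.09, adjusted p = 0.000158), while PHO5 (0.88 ± 0.11, adjusted p = 1.79e-06), PHO84 (2.34 ± 0.42, adjusted p = 0.000172) and RNR3 (0.92 ± 0.14, adjusted p = 3.97e-05) rose. ARG1, CUP9 and UBR1 were not called. HTB1 (−0.19 ± 0.08, adjusted p = 0.0419) lost its call without WT replicate 1 or 3 or bre1Δ replicate 1 or 2. STE3 (−0.23 ± 0.08, adjusted p = 0.0299) lost it without WT replicate 1 or bre1Δ replicate 1.

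P43L was compared with WT. INO1 fell to 414 ± 49.1 CPM (−1.21 ± 0.10, adjusted p = 1.57e-07), and the G1 cyclin genes PCL1 (−1.05 ± 0.12, adjusted p = 2.81e-05) and CLN1 (−0.88 ± 0.10, adjusted p = 2.81e-05) fell with it. KTR2 (−0.81 ± 0.17) and the thiamine regulator gene THI2 (−0.74 ± 0.08) were also lower. The agglutinin anchor gene AGA1 rose from 12.3 ± 1.51 to 26.2 ± 1.56 CPM (1.09 ± 0.13, adjusted p = 2.81e-05), and COS7, of a family of similar genes, rose by 1.22 ± 0.19. The mitochondrial ribosomal RNA 21S_RRNA rose by 1.25 ± 0.25 and the nuclear gene MRPS12 to 40.0 ± 8.30 CPM, the second a call lost without P43L replicate 1. SNR7-L (1.41 ± 0.43, adjusted p = 0.0499) overlaps SNR7-S and lost its call when any 1 of the 6 libraries was left out. In all, 683 genes changed, 335 up and 348 down (176 and 353 with library totals alone), 21 of them at least 2-fold (11 up, 10 down). Values of P43L and WT did not overlap in 655 called genes and in 33.9% of tested genes (10% by chance). The count depended on single libraries: it was 1109 without P43L replicate 2, 213 without P43L replicate 1, 222 without P43L replicate 3, 193 without WT replicate 2 and 277 without WT replicate 3.

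The iron regulon rose in P43L, with 10 of 26 genes up and none down (10 and 1 adjusted over the list alone; camera adjusted p = 2.69e-07, adjusted p = 0.144 with an estimated correlation). Examples were the cell wall mannoproteins FIT3 (0.76 ± 0.09) and FIT2 (0.63 ± 0.10) and the siderophore transporters SIT1 (0.56 ± 0.09) and ARN1 (0.52 ± 0.09). Genes of G2/M and M/G1 rose in 9 of 29 cases with no fall (11 adjusted over the list alone; camera adjusted p = 1.17e-06, adjusted p = 0.144 with an estimated correlation). Among them were the cell separation genes CTS1 (0.81 ± 0.11), DSE1 (0.59 ± 0.08) and DSE4 (0.50 ± 0.10). Ribosome biogenesis genes fell in 16 of 65 cases with no rise (20 adjusted over the list alone; camera adjusted p = 1.27e-08, adjusted p = 0.379 with an estimated correlation). RPF1 fell by 0.59 ± 0.12, RLP7 by 0.57 ± 0.10, RLP24 by 0.49 ± 0.10 and IMP4 by 0.45 ± 0.09. Pheromone response and haploid-specific genes rose in 7 of 25 cases and fell in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000214, adjusted p = 0.144 with an estimated correlation). With them were PRM1 (0.72 ± 0.15) and KAR4 (0.39 ± 0.09) beside AGA1. Thiamine synthesis genes fell in 4 of 18 cases with no rise (6 and 1 adjusted over the list alone; camera adjusted p = 0.000234, adjusted p = 0.234 with an estimated correlation). THI20 fell by 0.67 ± 0.07 and PET18 by 0.62 ± 0.10. Genes of G1/S and S phase fell in 4 of 25 cases with no rise, also adjusted over the list alone (camera adjusted p = 0.0250, adjusted p = 0.160 with an estimated correlation; lost without WT replicate 1), including SVS1 (−0.58 ± 0.10).

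The other 6 lists called in P43L also passed only with the preset correlation. Glycolysis (4 of 17 up, adjusted p = 2.10e-05, adjusted p = 0.430 with an estimated correlation), stress and storage carbohydrate (7 of 39 up, 0.000600 and 0.430), stress chaperones (3 of 25 up, 0.00221 and 0.207), ergosterol synthesis (10 of 25 up, 1 down, 0.00225 and 0.437) and nitrogen catabolite repression (6 of 24 up, 1 down, 0.00226 and 0.256) had more rises than falls. In the same order, 8, 12, 3, 12 and 11 rose adjusted over the list alone, with 2 falls each in the last 2. Only 1 of the 39 stress and storage carbohydrate genes rose with library totals alone. Meiosis genes fell in 3 of 41 cases, also adjusted over the list alone (0.0272 and 0.308), a call lost with library totals alone. PTR2 had 3.79 ± 1.07 CPM (0.34 ± 0.29, adjusted p = 0.446) and HTB2 a log2 fold change of −0.17 ± 0.08 (adjusted p = 0.169), and neither was called, nor were RNR3, PHO84, ARG1, CUP9 and UBR1. PHO5 (0.35 ± 0.11, adjusted p = 0.0374) and STE3 (0.33 ± 0.08, adjusted p = 0.0149) each lost their call without WT replicate 2 or 3 or P43L replicate 1 or 3.

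P47T was compared with WT. Under the naming rule, the lowest fold changes were those of the mitochondrially encoded genes and small nucleolar RNAs given next. Nuclear noncoding genes as a set went both ways in P47T, with 18 of 91 up, 14 down and a median of 0.12. BI4 (−2.45 ± 0.55, adjusted p = 0.00631), AI5_ALPHA (−1.54 ± 0.23, adjusted p = 0.000107) and ATP6 (−1.49 ± 0.37, adjusted p = 0.0113) fell, the first 2 lying within other genes, as did SNR77 (−2.06 ± 0.45, adjusted p = 0.00475) and SNR56 (−1.44 ± 0.31, adjusted p = 0.00245). MRPS12 rose from 16.2 ± 1.47 to 49.8 ± 1.81 CPM (1.61 ± 0.28, adjusted p = 0.000930). The noncoding RNAs SNR161 (1.89 ± 0.50), SNR5 (1.84 ± 0.53), SNR7-L (1.69 ± 0.43) and SNR49 (1.62 ± 0.43) rose as well, but all 4 lost their call without P47T replicate 1. SNR5 also lost it without P47T replicate 2, SNR5 and SNR49 without WT replicate 1 or 3, and SNR161 without WT replicate 2. Among nuclear protein-coding genes, chosen after their values were seen, the mating-type endonuclease gene HO (1.24 ± 0.13, adjusted p = 6.23e-06), PLB2 (1.07 ± 0.12, adjusted p = 1.04e-05) and the phospholipid regulator gene INO2 (0.98 ± 0.11) rose. INO2 also rose in P43L (0.79 ± 0.11) and E49K (0.76 ± 0.11) and fell in rad6Δ (−0.54 ± 0.12). In P47T the one-carbon gene MTD1 (−1.13 ± 0.11, adjusted p = 8.84e-07) and the purine gene ADE17 (−0.94 ± 0.09, adjusted p = 8.84e-07) fell. In all, 1569 genes changed, 799 up and 770 down, 61 at least 2-fold (24 up, 37 down). The count was 959 without P47T replicate 1 and 1017 without P47T replicate 2. With library totals alone the split was 407 up and 1297 down, and the median of all genes moved to −0.13. Values of P47T and WT did not overlap in 1493 called genes and in 43.4% of tested genes (10% by chance).

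Ribosomal protein genes rose in P47T in 99 of 137 cases with no fall (109 adjusted over the list alone; camera adjusted p = 1.32e-31, adjusted p = 0.159 with an estimated correlation). Examples were RPL1A (0.93 ± 0.11), RPS24A (0.88 ± 0.12), RPS28A (0.88 ± 0.12) and RPS14A (0.68 ± 0.09), all from gene pairs whose reads are uncertain. Respiration and TCA cycle genes fell in 22 of 43 cases with no rise (23 adjusted over the list alone; camera adjusted p = 1.87e-08, adjusted p = 0.144 with an estimated correlation). CYT1 fell by 0.57 ± 0.07, ATP14 by 0.54 ± 0.08, COR1 by 0.44 ± 0.07 and the citrate synthase gene CIT1 by 0.42 ± 0.06. Mitochondrially encoded transcripts fell in 11 of 21 cases and rose in 2 (13 and 4 adjusted over the list alone; camera adjusted p = 0.00236, adjusted p = 0.387 with an estimated correlation), and mitochondrial genes took 1.07% ± 0.072 of the counts against 1.57% ± 0.031 in WT. Glycolysis genes rose in 11 of 17 cases with no fall (12 adjusted over the list alone; camera adjusted p = 5.59e-07, adjusted p = 0.373 with an estimated correlation). ENO2 rose by 0.94 ± 0.16, TPI1 by 0.73 ± 0.15 and FBA1 by 0.64 ± 0.13. Ergosterol synthesis genes rose in 12 of 25 cases with no fall (13 adjusted over the list alone; camera adjusted p = 1.87e-06, adjusted p = 0.256 with an estimated correlation). Among them were ERG11 (0.81 ± 0.12), ERG25 (0.78 ± 0.09) and ERG3 (0.67 ± 0.10). Gcn4 amino acid genes rose in 24 of 52 cases and fell in 2 (29 and 2 adjusted over the list alone, 14 and 2 with library totals alone; camera adjusted p = 1.18e-06, adjusted p = 0.387 with an estimated correlation). LEU9 rose by 0.85 ± 0.12 and HOM3 by 0.57 ± 0.09, while SER3 was lower (−0.39 ± 0.08). Stress and storage carbohydrate genes fell in 18 of 39 cases with no rise (22 adjusted over the list alone; camera adjusted p = 1.25e-07, adjusted p = 0.256 with an estimated correlation). GPH1 fell by 0.59 ± 0.10 and GAC1 by 0.51 ± 0.07.

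The other 6 lists called in P47T also passed only with the preset correlation. Rises outnumbered falls in G2/M and M/G1 genes (13 of 29 up, 1 down, adjusted p = 3.42e-05, adjusted p = 0.159 with an estimated correlation), ribosome biogenesis (21 of 65 up, 1 down, 6.65e-05 and 0.538), the zinc regulon (5 of 14 up, 0.00796 and 0.441) and G1/S and S-phase genes (7 of 25 up, 2 down, 0.0175 and 0.159). In the same order, 15, 21, 8 and 10 rose adjusted over the list alone, with 1, 1, 1 and 2 falls. With library totals alone these lists had fewer rises, at 5 up and 2 down, 12 and 2, 2 and 2, and 4 and 3, and the ribosome biogenesis median was 0.01. Falls outnumbered rises in glucose-repressed genes (6 of 30 down, 1 up, 5 and 1 adjusted over the list alone, 10 and 0 with library totals alone, 0.00439 and 0.209) and in meiosis genes (9 of 41 down, 5 adjusted over the list alone, 0.0334 and 0.352), the last lost without WT replicate 2 or P47T replicate 1 and with library totals alone. Of the genes followed in every strain only ARG1 was called (0.33 ± 0.09, adjusted p = 0.00973), a call lost without P47T replicate 1 and with library totals alone. PTR2 (0.55 ± 0.28, adjusted p = 0.148), HTB2 (0.18 ± 0.08, adjusted p = 0.111), PHO5 (−0.02 ± 0.11, adjusted p = 0.922) and RNR3 (0.36 ± 0.15, adjusted p = 0.0707) were not.

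E49K was compared with WT. VEL1 (chromosome VII, 11110 to 11730) rose from 4.22 ± 1.72 to 55.9 ± 22.9 CPM (3.71 ± 0.40, adjusted p = 2.88e-05), THI4 to 31.8 ± 2.14 CPM (2.54 ± 0.15, adjusted p = 2.92e-10) and CSS1 to 36.2 ± 1.88 CPM (2.17 ± 0.25, adjusted p = 2.28e-05). The amino acid permease gene DIP5 (1.56 ± 0.16, adjusted p = 6.33e-07) and the flocculation gene FLO1 (1.31 ± 0.15), both chosen after their values were seen, rose too. BI4 (−2.27 ± 0.53, adjusted p = 0.00733), SNR77 (−1.84 ± 0.43, adjusted p = 0.00605), ATP6 (−1.58 ± 0.37, adjusted p = 0.00724) and AI5_ALPHA (−1.36 ± 0.22, adjusted p = 0.000171) fell. QCR6 (−1.11 ± 0.14, adjusted p = 1.98e-05) and the ATPase inhibitor gene INH1 (−1.10 ± 0.11, adjusted p = 5.43e-07), chosen after their values were seen, fell with them. Calls for SNR5 (1.74 ± 0.53), SNR13 (1.71 ± 0.47) and SNR67 (−1.30 ± 0.35) rested on single libraries. SNR5 lost its call without WT replicate 1 or 3 or E49K replicate 2 or 3, SNR13 without WT replicate 3 or E49K replicate 3, and SNR67 without WT replicate 2 or E49K replicate 1. In all, 1765 genes changed, 857 up and 908 down (538 and 952 with library totals alone), 75 at least 2-fold (49 up, 26 down). Values of E49K and WT did not overlap in 1729 called genes and in 49.9% of tested genes (10% by chance).

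The iron regulon rose in E49K in 17 of 26 cases with 1 fall (20 and 1 adjusted over the list alone; camera adjusted p = 6.91e-18, adjusted p = 0.0326 with an estimated correlation). FIT2 rose by 1.55 ± 0.10, FIT3 by 1.45 ± 0.09 and the heme oxygenase gene HMX1 by 0.92 ± 0.09, and ARN1 rose with them (adjusted p = 1.01e-08). Respiration and TCA cycle genes fell in 27 of 43 cases and rose in 1 (31 and 1 adjusted over the list alone; camera adjusted p = 6.61e-14, adjusted p = 0.0667 with an estimated correlation). CYT1 fell by 0.91 ± 0.07, QCR10 by 0.86 ± 0.10, QCR8 by 0.81 ± 0.10 and MDH1 by 0.57 ± 0.07. Mitochondrially encoded transcripts fell in 12 of 21 cases with no rise (12 and 2 adjusted over the list alone; camera adjusted p = 0.00236, adjusted p = 0.387 with an estimated correlation). COX3 fell by 0.59 ± 0.13, and mitochondrial genes took 1.11% ± 0.080 of the counts. Thiamine synthesis genes rose in 11 of 18 cases and fell in 1, also adjusted over the list alone (camera adjusted p = 8.58e-08, adjusted p = 0.144 with an estimated correlation). THI73 was at 1.59 ± 0.12 and THI6 at 0.58 ± 0.08. Glycolysis genes rose in 13 of 17 cases with no fall, also adjusted over the list alone (camera adjusted p = 2.02e-06, adjusted p = 0.387 with an estimated correlation). Examples were PDC5 (0.76 ± 0.15) and TDH1 (0.71 ± 0.12). Stress and storage carbohydrate genes fell in 20 of 39 cases with no rise (24 adjusted over the list alone; camera adjusted p = 4.00e-07, adjusted p = 0.259 with an estimated correlation). ALD3 fell by 0.89 ± 0.12, GLG1 by 0.68 ± 0.10 and CTT1 by 0.66 ± 0.09. Zinc genes rose in 7 of 14 cases with no fall, also adjusted over the list alone (camera adjusted p = 0.000191, adjusted p = 0.305 with an estimated correlation). ZPS1 was at 1.24 ± 0.17, ZRT3 at 0.70 ± 0.11 and IZH1 at 0.59 ± 0.11.

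The other 10 lists called in E49K passed only with the preset correlation. Rises outnumbered falls in cell wall integrity (14 of 31 up, 2 down, adjusted p = 0.000118, adjusted p = 0.387 with an estimated correlation), Gcn4 amino acid biosynthesis (16 of 52 up, 1 down, 0.000770 and 0.554), ribosomal proteins (34 of 137 up, 5 down, 0.00165 and 0.655) and sulfur amino acid metabolism (9 of 30 up, 1 down, 0.00889 and 0.256). In the same order, 17, 18, 34 and 10 rose adjusted over the list alone, with 2, 1, 5 and 1 falls. The same held for ribosome biogenesis (17 of 65 up, 1 down, 0.00241 and 0.649) and ergosterol synthesis (7 of 25 up, 2 down, 0.0250 and 0.578), both lost without E49K replicate 2, and for G2/M and M/G1 genes (13 of 29 up, 4 down, 0.0239 and 0.366), lost without WT replicate 3. For these 3, 16, 7 and 14 rose adjusted over the list alone, with 0, 2 and 4 falls. Gcn4 genes had 9 rises and 3 falls with library totals alone, G2/M and M/G1 genes 8 and 3, and genes within 20 kb of a chromosome end 25 and 16. Subtelomeric families (7 of 34 up, 1 down, also adjusted over the list alone, 0.0459 and 0.256) lost their call without E49K replicate 3, and genes within 20 kb of a chromosome end (30 of 135 up, 14 down, 31 and 16 adjusted over the list alone, 0.0482 and 0.264) without WT replicate 1, WT replicate 2 or E49K replicate 3. Histone genes fell in 4 of 11 cases, 5 adjusted over the list alone (0.0323 and 0.234), a call lost without E49K replicate 1 or 2. PHO5 rose (1.21 ± 0.10, adjusted p = 3.53e-08), as did PHO84 (1.83 ± 0.43, adjusted p = 0.00326) and RNR3 (0.84 ± 0.14, adjusted p = 0.000180). PTR2 (0.75 ± 0.27, adjusted p = 0.0374), HTB2 (−0.27 ± 0.08, adjusted p = 0.0198) and ARG1 (0.25 ± 0.09, adjusted p = 0.0403) passed the threshold only narrowly. PTR2 lost its call without WT replicate 1 or 3 or any 1 E49K library, HTB2 without WT replicate 1 or E49K replicate 1 or 3, and ARG1 without any 1 of the 6.

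**Figure D3:**
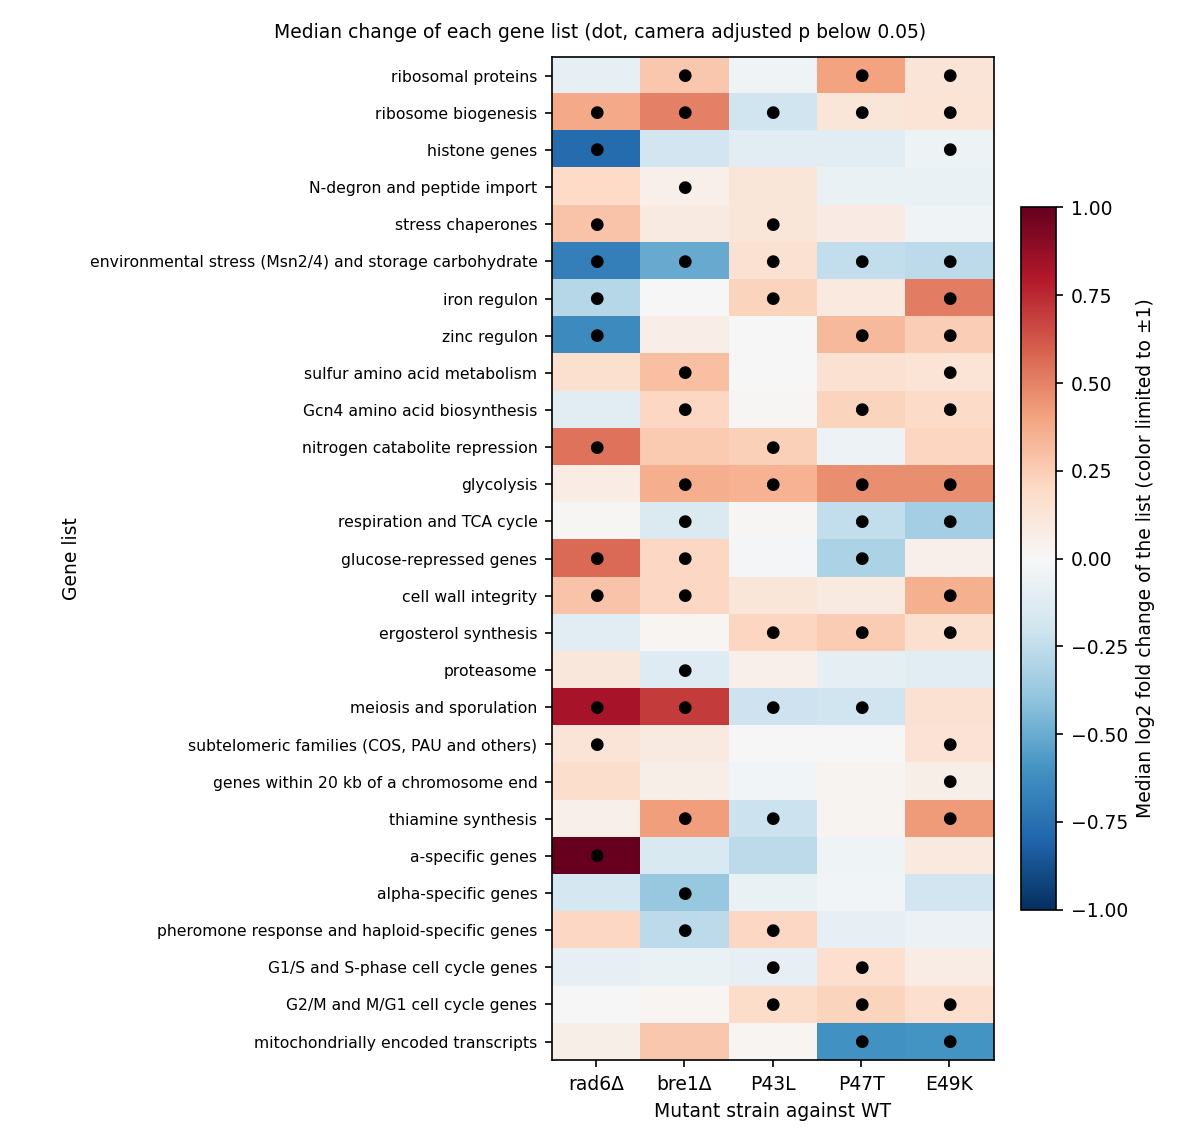
Median log2 fold change against WT (color, limited to ±1) of each gene list that was called in at least 1 mutant, by strain, with a dot where the camera adjusted p was below 0.05 with the preset correlation. Stress and storage carbohydrate genes have negative medians in rad6Δ (−0.68), bre1Δ (−0.51), P47T (−0.25) and E49K (−0.26) and a positive one in P43L (0.15).

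Fold changes of the mutants were set side by side. In rad6Δ and bre1Δ, 864 genes were higher in both and 895 lower in both, where independent lists would share 312 and 309, and 31 went opposite ways. Groups simulated with no effect around a shared simulated WT group shared no calls here and at most 0.05 on average for any pair. Genes varied independently in them, so they set no bound on calls shared through the real WT libraries. The correlation across genes was 0.755 (0.508 simulated with no effect), and the covariance exceeded the simulated one by 0.149. A simulated correlation, here and for the pairs below, comes from noise with a shared WT group. Real effects add variance, so an observed correlation cannot be compared directly with it. The covariance difference is not affected in this way. In rad6Δ and E49K, 524 genes were higher in both and 572 lower in both (213 and 225 for independent lists), 68 went opposite ways, and the correlation was 0.563 (0.523 simulated; covariance difference 0.0867). P47T shared 282 higher and 309 lower genes with rad6Δ (199 and 191 for independent lists), with 223 in opposite directions and a correlation of 0.199 (0.512 simulated; covariance difference 0.0210). P43L shared 125 and 156 (83.2 and 86.4 for independent lists), with 113 opposite and a correlation of 0.249 (0.509 simulated; covariance difference 0.0213). The 281 genes that P43L shared with rad6Δ in direction became 84 without WT replicate 2 and 124 without WT replicate 3. Part of each excess may come from the shared WT libraries, and genes are not independent replicates. Both null strains also carry the empty vector, while WT and the point mutants carry the plasmid with RAD6. An effect of the vector on the agreement of the null strains cannot be told apart from that of the deletions.

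Over all genes, the slope of a mutant's fold changes on those of rad6Δ was 0.666 for bre1Δ (0.671 to 0.690 with 1 WT library left out), 0.387 for E49K (0.396 to 0.404), 0.095 for P43L (0.097 to 0.109) and 0.094 for P47T (0.087 to 0.107). Only bre1Δ shares the empty vector with rad6Δ, so its slope may hold an effect of the vector that the slopes of the point mutants lack. Of the 2796 genes changed in rad6Δ, 1096 (39.2%) changed in the same direction in E49K, 591 (21.1%) in P47T and 281 (10.1%) in P43L. Those that changed in the opposite direction numbered 68, 223 and 113. Such shares depend on how many genes each strain had called against WT, which was 1765, 1569 and 683. Tested directly, 1450 of the 2796 differed between E49K and rad6Δ, 1426 of them toward WT. Toward WT gives only the direction of the difference from rad6Δ, so genes that passed beyond WT are counted as well. For P47T 1945 differed (1924 toward WT), and for P43L 2030 (2022 toward WT). Choosing genes with the same rad6Δ libraries pushes differences toward WT. In 20 simulations, added after seeing the data, of point mutants with the means of rad6Δ, at most 2 chosen genes were called. Of all chosen genes, called or not, 56.9% to 57.2% on average lay toward WT in the simulations, against 95.4% in P43L, 92.9% in P47T and 88.8% in E49K.

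**Figure D4:**
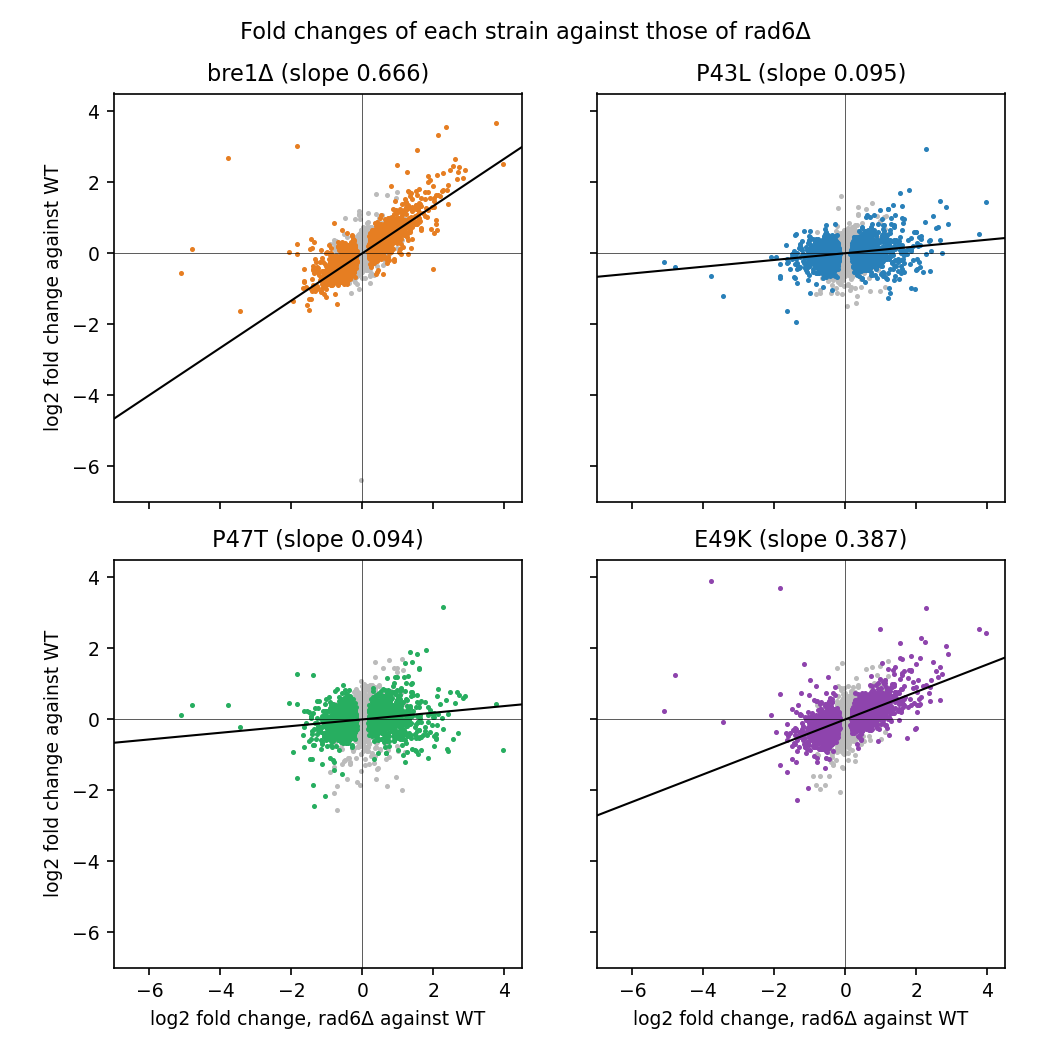
Log2 fold change against WT of each tested gene in bre1Δ, P43L, P47T and E49K (vertical axes) against that in rad6Δ (horizontal axes), with genes called in rad6Δ in color, other genes in grey and a black line through the origin with the slope corrected for the shared WT error. The slopes are 0.666 for bre1Δ, 0.387 for E49K, 0.095 for P43L and 0.094 for P47T.

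The same comparison was made with bre1Δ and between the point mutants. E49K shared 552 higher and 577 lower genes with bre1Δ (191 and 201 for independent lists), with 25 opposite and a correlation of 0.658 (0.493 simulated; covariance difference 0.0880). P47T shared 371 and 327 with bre1Δ (178 and 170), with 138 opposite (0.263, 0.491 simulated; covariance difference 0.0256), and the 698 together became 444 without WT replicate 3. P43L shared 127 and 113 with bre1Δ (74.8 and 76.9), with 113 opposite (0.213, 0.487 simulated; covariance difference 0.0127), and the 240 became 58 and 87 without WT replicate 2 or 3. P47T and E49K shared 391 higher and 418 lower genes (122 and 124), with 26 opposite (0.615, 0.512 simulated; covariance difference 0.0601), and the 809 became 516 and 495 without WT replicate 2 or 3. P43L shared 160 and 148 with E49K (51.0 and 56.1), with 28 opposite (0.517, 0.519 simulated; covariance difference 0.0369), and the 308 became 76 and 100. It shared 131 and 99 with P47T (47.5 and 47.6), with 31 opposite (0.473, 0.502 simulated; covariance difference 0.0302), and the 230 became 64 and 71. In all 5 mutants 30 genes rose, among them ERG11, ERG13, the urea amidolyase gene DUR12, TRP2 and FLO1, and 28 fell, among them HHF1, PCL1, INH1 and RAD23, examples chosen after their values were seen. Independent lists give 0.402 and 0.421 such genes and the simulated groups gave 0, but the 5 comparisons share the WT libraries. The 30 became 24, 7 and 11 without WT replicate 1, 2 or 3, and the 28 became 23, 8 and 12.

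The point mutants were compared directly with rad6Δ. ZPS1 was higher than in rad6Δ in P43L (4.43 ± 0.22, adjusted p = 1.34e-10), P47T (5.22 ± 0.23, adjusted p = 2.06e-11) and E49K (6.04 ± 0.23, adjusted p = 6.61e-12). INO1 was higher by 2.23 ± 0.10 in P43L, 3.21 ± 0.11 in P47T and 3.36 ± 0.11 in E49K, and MLS1 was lower, at −2.31 ± 0.15, −3.06 ± 0.17 and −2.12 ± 0.14. ZRT1 (1.99 ± 0.10), PDH1 (−2.33 ± 0.15) and DPA10 (−2.18 ± 0.19) also led the differences of P43L. VEL1 (3.11 ± 0.61), LOH1 (−2.77 ± 0.20) and POT1 (−2.61 ± 0.23) led those of P47T, and VEL1 (5.55 ± 0.49), LOH1 (−1.81 ± 0.17) and PDH1 (−1.67 ± 0.14) those of E49K. In all, 2762 genes differed from rad6Δ in P43L (1346 higher, 1416 lower; 293 at least 2-fold), 2943 in P47T (1459 and 1484; 309) and 2076 in E49K (1034 and 1042; 143). With library totals alone the P47T split was 1056 and 1816, and its median moved to −0.10. The 3 comparisons share the rad6Δ libraries. The groups did not overlap in 56.4%, 59.7% and 51.3% of all tested genes, where chance gives 10%, and in 2644, 2834 and 2006 called genes. Histone genes were higher than in rad6Δ in 10 of 11 cases in P43L with 1 lower (camera adjusted p = 1.89e-05, adjusted p = 0.0252 with an estimated correlation), in 9 with 1 lower in P47T (3.52e-05 and 0.0272) and in 9 with none lower in E49K (4.98e-05 and 0.0291). Meiosis genes were lower in 31 of 41 cases in P43L (9.52e-09 and 0.0291), 31 in P47T (7.54e-09 and 0.0331) and 26 in E49K (1.62e-06 and 0.0377), with 2 higher each time.

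The null strains were compared with each other. ZPS1 (−4.91 ± 0.23, adjusted p = 1.87e-10), VEL1 (−4.86 ± 0.52, adjusted p = 2.44e-05) and ZRT1 (−2.11 ± 0.10, adjusted p = 1.02e-12) were lower in rad6Δ than in bre1Δ, and the chaperone gene SSA3 (1.33 ± 0.09, adjusted p = 1.10e-09), PDH1 (1.25 ± 0.14) and POT1 (1.13 ± 0.20) were higher. Zinc genes were lower in 10 of 14 cases with none higher (camera adjusted p = 5.27e-25, adjusted p = 0.0145 with an estimated correlation) and histone genes in 8 of 11 with none higher (1.05e-07 and 0.00971). Proteasome genes were higher in 19 of 33 cases with none lower (5.62e-09 and 0.00971). Ribosomal protein genes were lower in 96 of 137 cases with none higher (1.45e-26 and 0.102). In all, 1170 genes differed, 502 higher and 668 lower in rad6Δ, 51 at least 2-fold, with a split of 770 and 356 under library totals alone. The groups did not overlap in 32.6% of all tested genes, where chance gives 10%, and in 1089 called genes. A fit of these 6 libraries by themselves called 748. Both strains carry the empty vector, and bre1Δ keeps its own untagged chromosomal RAD6.

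The point mutants were compared with one another. P43L had lower ribosomal protein transcripts than P47T in 120 of 137 cases with none higher (camera adjusted p = 3.43e-33, adjusted p = 0.0728 with an estimated correlation) and higher respiration transcripts in 23 of 43 cases with 1 lower (5.30e-09 and 0.0511). FUS2 (1.12 ± 0.19, adjusted p = 0.000225) was higher in P43L, and ADH4 (−1.14 ± 0.16, adjusted p = 9.49e-05) and RFU1 (−1.13 ± 0.19, adjusted p = 0.000172) were lower. BI4 (1.62 ± 0.55, adjusted p = 0.0426) lost its call without any 1 of P43L replicates 1 and 2 or of the P47T libraries, COB (1.22 ± 0.37, adjusted p = 0.0250) without P43L replicate 1 or 2 or P47T replicate 3, and VEL1 (−1.58 ± 0.50, adjusted p = 0.0283) without P43L replicate 1 or 3 or P47T replicate 2 or 3. In all, 1743 genes differed, 825 higher and 918 lower in P43L (1003 and 563 with library totals alone), 30 at least 2-fold. Against E49K, P43L was lower in THI4 (−2.86 ± 0.16, adjusted p = 5.47e-11), VEL1 (−4.03 ± 0.41) and THI73 (−1.72 ± 0.12) and higher in AGA1 (1.06 ± 0.13) and RPM2 (1.02 ± 0.09). ATP6 (1.11 ± 0.37, adjusted p = 0.0449) lost its call without P43L replicate 2 or any 1 E49K library. Respiration transcripts were higher in P43L in 28 of 43 cases with 1 lower (1.60e-17 and 0.0145). In all, 1429 genes differed (698 higher, 731 lower; 44 at least 2-fold), and 933 without E49K replicate 2. P47T was lower than E49K in THI4 (−2.89 ± 0.15, adjusted p = 3.54e-11), VEL1 (−2.44 ± 0.34) and CSS1 (−2.14 ± 0.25) and higher in the dicarboxylate carrier gene DIC1 (1.03 ± 0.10), HO (1.02 ± 0.13) and SPR6 (0.96 ± 0.22). Iron genes were lower in P47T in 13 of 26 cases with none higher (3.69e-19 and 0.00971), and ribosomal protein genes higher in 61 of 137 with none lower (1.68e-18 and 0.159). In all, 1000 genes differed (530 higher, 470 lower; 258 and 571 with library totals alone; 63 at least 2-fold), and 567 without E49K replicate 1 or 663 without P47T replicate 1. In these 3 comparisons the groups did not overlap in 41.9%, 42.5% and 37.0% of all tested genes, where chance gives 10%, and in 1649, 1375 and 984 called genes.

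**Figure D5:**
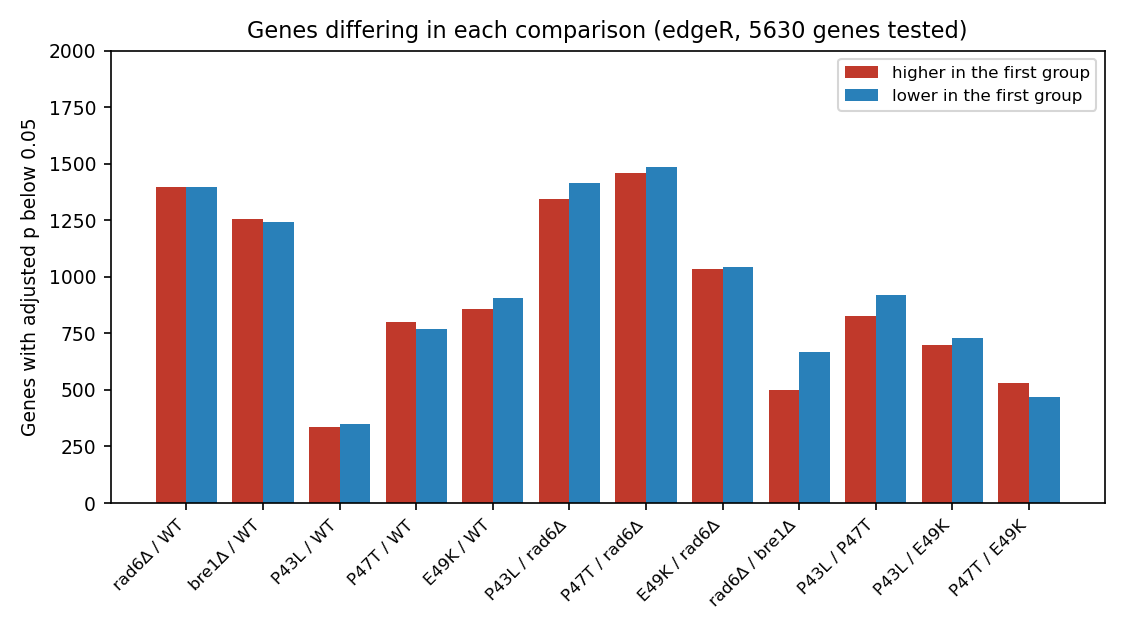
Number of genes with an adjusted p below 0.05 in each of the 12 comparisons, with red bars for genes higher and blue bars for genes lower in the first-named strain. The bars are highest for P47T against rad6Δ (1459 and 1484) and lowest for P43L against WT (335 and 348).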

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

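Of the tests in this part, the direct tests of gene lists between mutants, those of TRP1 and GEP7 against the plasmid, of GEP7 against the chromosomal deletion, of mating type and of RNA without a poly(A) tail, and the thinning of libraries, were chosen only after the result was seen. The following gene lists were marked because they were called in opposite directions against WT in 2 mutants and a direct test between those 2 groups passed, each with the preset correlation. Opposite calls from the same libraries already imply a difference between the 2 mutants. The direct tests of these lists are therefore not separate evidence, and their p-values carry this selection. Values are list medians of log2 fold change, first strain minus second, and adjusted p values here are those with an estimated correlation. Ribosome biogenesis genes were lower in P43L than in rad6Δ (−0.59), P47T (−0.35) and E49K (−0.33), and none of the 3 passed with an estimated correlation (adjusted p = 0.136, 0.149 and 0.159). Stress and storage carbohydrate genes were higher in P43L than in rad6Δ (0.83), P47T (0.38) and E49K (0.44), and again none passed with an estimated correlation (adjusted p = 0.0504, 0.0728 and 0.0614). Iron genes were higher than in rad6Δ in P43L (0.52, adjusted p = 0.0365) and E49K (0.71, adjusted p = 0.00465), and zinc genes in P47T (0.82, adjusted p = 0.0400) and E49K (0.85, adjusted p = 0.0145). Meiosis genes were lower than in rad6Δ in P43L (−1.10, adjusted p = 0.0291) and P47T (−0.97, adjusted p = 0.0331), and glucose-repressed genes in P47T (−0.77, adjusted p = 0.0170). Thiamine synthesis genes were lower in P43L than in E49K (−0.73, adjusted p = 0.00971), and G1/S and S-phase genes lower in P43L than in P47T (−0.27, adjusted p = 0.0145).

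TRP1 and GEP7 were lower in both null strains, which carry the empty vector. TRP1, the marker of the plasmid, had at most 379 CPM in the 6 null libraries and at least 499 CPM in the other 12, while the lower of the 2 medians of TRP2 to TRP5 was 0.30 (rad6Δ: TRP2 0.56, TRP3 0.06, TRP4 −0.29 with adjusted p = 0.00512, TRP5 0.54), against a fall of the pathway as a whole. GEP7, 461 bases from RAD6, had at most 15.8 CPM in the null libraries and at least 26.5 CPM elsewhere. WT and rad6Δ share the deletion of chromosomal RAD6, and GEP7 still differed between them (−1.50 ± 0.17, adjusted p = 4.63e-07), which does not point to that deletion. A difference between the plasmids could account for lower values of both genes, but each strain with the empty vector also lacks RAD6 or BRE1, so an effect of the mutations stays open. TRP1 also differed between the null strains without overlap (342 ± 52.4 CPM in rad6Δ, 210 ± 22.9 CPM in bre1Δ), which their shared empty vector by itself does not account for.

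Mitochondrially encoded transcripts were lower in P47T and E49K, with medians of −0.60 ± 0.25 and −0.59 ± 0.21 over 21 genes. Each ± of these medians is a standard error from the spread across genes, not across libraries. Some of the genes overlap and they are not independent replicates, so these errors are likely too small. Nuclear noncoding RNAs, which also lack a poly(A) tail in most cases, had medians of 0.12 and 0.07 over 91 genes, but these went both ways (18 up and 14 down, 14 up and 16 down), so a lower yield of such RNA stays open. With every library thinned to 5065845 counts the mitochondrial medians were −0.64 and −0.62. Fold changes are already scaled to library totals, and random thinning does not shift their expected value, so this cannot decide on a difference in depth. Fewer mitochondrial transcripts in these mutants also remain a candidate explanation, and neither list call passed with an estimated correlation (adjusted p = 0.387 in both).

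The mating-type transcripts did not match the labels, which give mating type a for the strains. The lowest ratio of MF(ALPHA)1 to MFA1 plus MFA2 in any library was 450, which fits alpha cells in every strain. The lowest value of STE3, STE4, GPA1 and FUS3 in any library was 47.8 CPM, against diploid cells. The a-factor transcripts lay between 0.14 and 3.31 CPM. They were highest in rad6Δ (2.23 to 3.31 CPM, at most 1.32 CPM elsewhere), where the ratio was 450 to 677, against 1146 or more in the other strains. With so few a-factor reads the size of the ratio is imprecise in every group.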

How the results depend on the processing

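No test in this part was chosen after the result was seen except 2 alternatives, which left out the 3 libraries farthest from their own group or thinned all libraries to the lowest total. No named gene reversed: of 305 results 252 were called, and 26 of these lost the call in some alternative, and the cause was not tested. DESeq2 called 2738, 2430, 830, 1564 and 1745 genes in rad6Δ, bre1Δ, P43L, P47T and E49K against WT. At an adjusted p below 0.01 the counts were 1661 for bre1Δ, 166 for P43L, 778 for P47T, 933 for E49K, 1322 for E49K against rad6Δ, 605 for rad6Δ against bre1Δ, 1018 for P43L against P47T, 782 for P43L against E49K and 443 for P47T against E49K. Changes in the same direction at 0.01 numbered 61, 266 and 564 for P43L, P47T and E49K with rad6Δ, 46, 295 and 565 with bre1Δ, 41 for P43L with P47T, 62 for P43L with E49K and 340 for P47T with E49K. A fold of at least 2 left 262, 123, 21, 61 and 75 genes against WT, 293, 309 and 143 for the point mutants against rad6Δ, 51 for rad6Δ against bre1Δ, and 30, 44 and 63 between point mutants. A stricter threshold lowers counts by construction. Of 69 list calls, 2 remained with an estimated correlation. A fit of the 2 groups alone gave 748 for rad6Δ against bre1Δ, and P43L had 1473 calls without the 3 libraries farthest from their group; the cause was not tested.

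With 1 library left out, calls ranged from 2429 to 2536 for rad6Δ, 2033 to 2534 for bre1Δ, 193 to 1109 for P43L, 959 to 1596 for P47T and 1184 to 1484 for E49K. They ranged from 2439 to 2638, 2615 to 2738 and 1665 to 1789 for P43L, P47T and E49K against rad6Δ, and 783 to 1092 for rad6Δ against bre1Δ. Between point mutants they ranged from 1253 to 1718 (P43L and P47T), 933 to 1320 (P43L and E49K) and 567 to 815 (P47T and E49K), and list calls from 67 to 72. Shared directions ranged from 1461 to 1491 for rad6Δ with bre1Δ, 84 to 216, 394 to 426 and 767 to 869 for rad6Δ with P43L, P47T and E49K, and 58 to 170, 444 to 501 and 770 to 887 for bre1Δ with them. Between point mutants they ranged from 64 to 176, 76 to 229 and 495 to 575. Genes changed in rad6Δ that differed from it ranged from 1775 to 1917 in P43L, 1696 to 1862 in P47T and 1194 to 1346 in E49K. Fewer libraries give less power, which does not account for counts that rose, such as that of P43L from 683 to 1109 without P43L replicate 2.

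The libraries share only replicate numbers. With the replicate block, calls were 2718, 2389, 570, 1433 and 1618 against WT, 2675, 2867 and 2006 against rad6Δ, 1083 for rad6Δ against bre1Δ, 1651, 1318 and 884 between point mutants, and 69 for lists. Under the block, shared directions were 1683, 233, 539, 1015, 182, 632, 1023, 176, 233 and 714, and differing genes 1970, 1877 and 1399. The block ended the calls of RAD6, PTR2 and ARG1 in E49K, SNR7-L in P43L and HTB1 in bre1Δ and no other named call. Only 3 of 18 libraries correlated best with their own number (mean r −0.0205, 0.011 for other numbers), a hint from the data and not the design. Thinned to the lowest total, the libraries gave 2570, 2282, 516, 1291 and 1423 calls against WT.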

Other observations

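Of the tests in this part, none was chosen after its own result was seen, but each group of genes was picked because some of its members had been noticed. Phospholipid genes under Ino2 and Ino4 fell together in rad6Δ, beside INO1. SAM2 fell by 1.65 ± 0.09, ITR1 by 1.46 ± 0.09, OPI3 by 1.25 ± 0.16, HNM1 by 0.77 ± 0.13 and ACC1 by 0.67 ± 0.14. The hypothesis that the genes noticed belong to a group that moves together was tested on the 15 members other than INO1, ITR1, PSD1 and SAM2, of which 12 fell and 1 rose (adjusted p = 0.000209 over 15 tests, adjusted p = 0.0663 with an estimated correlation). The members not noticed fell as predicted with the preset correlation only. In bre1Δ, which shares the empty vector, ITR1 fell by 1.00 ± 0.08 and SAM2 by 0.43 ± 0.08. There 7 of the 15 members not noticed fell and 1 rose, without a call (adjusted p = 0.0646, adjusted p = 0.348 with an estimated correlation).

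Kynurenine genes of NAD synthesis were noticed in rad6Δ through BNA2 (1.82 ± 0.11) and BNA4 (0.97 ± 0.08), but the other members did not rise as a group (1 rose and 4 fell of 8, adjusted p = 0.303). Purine and one-carbon genes were noticed in P47T through ADE17, MTD1, ADE1 (−0.60 ± 0.08), GCV1 (−0.44 ± 0.08) and GCV2 (−0.34 ± 0.07). The same genes all fell in E49K too, GCV1 by 0.815 ± 0.076 and GCV2 by 0.594 ± 0.074, and all rose in rad6Δ. Only ADE17 and MTD1 of them were called in P43L, and only GCV1 and GCV2 in bre1Δ, all lower. In P47T the members not noticed did not fall as a group (3 rose and 3 fell of 16, adjusted p = 0.828). A p that misses the threshold does not show that there is no difference.

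The libraries of each comparison can be divided into groups of 3 in only 10 ways, too few for a share under 0.05. In all 12 comparisons 1 of the 10 divisions, the real one, reached the real count of calls. Every other division called 0 genes, except in rad6Δ against bre1Δ, where the highest other count was 2 against 1170. Each of these divisions mixes both strains within its groups, so strain differences widen the spread and lower the calls. Their counts are therefore not values for strains without a difference, and no conclusion is drawn from them.

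URA3 transcripts were higher than in WT in rad6Δ (adjusted p = 0.000673), bre1Δ (0.96 ± 0.30), P47T (1.43 ± 0.30) and E49K (1.24 ± 0.30), and P43L had 0.99 ± 0.30 (adjusted p = 0.0508). SDS23, 1530 bases from RAD6, had log2 fold changes of 0.65 in rad6Δ (adjusted p = 8.62e-06), 0.83 in bre1Δ (1.15e-06), −0.10 in P43L (0.511), 0.34 in P47T (0.0131) and 0.56 in E49K (0.000238). PKP2, 287 bases from RAD6, had −0.43 in rad6Δ (0.000155), −0.18 in bre1Δ (0.0651), −0.21 in P43L (0.0771), −0.29 in P47T (0.0106) and −0.27 in E49K (0.0136). Medians of single nuclear chromosomes lay between −0.0669 and 0.0915 in every comparison with WT.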
